A study of Mus musculus with 24 samples.

How the data were processed

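FAIRE-seq and RNA-seq were run on mouse liver from 2 strains and 3 diets, with 2 libraries per strain, diet and assay. Groups were taken from the sample titles. The diet tag of the Reversal samples gives 16 weeks of control diet, while the treatment protocol gives 8 weeks, and the protocol was followed. Nothing in the labels says that the libraries of a group came from separate animals. The deposited p-values therefore measure only the spread between these libraries, which may be technical. The p-values of Fisher's exact test and the binomial test count genes, which are not independent replicates, and measure no spread between libraries.

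The submitters' processing notes name mm9, Bowtie2, TopHat and DESeq2, with no version and no role. The peak caller is not given in the sources used here. Each of the 6 deposited peak lists gives a start, an end, a summit and a signal per peak, and this signal is the authors' own value on a scale that is not given. Strain and diet of each list are known from its name only, and whether the libraries of a group were pooled is not given in the sources used here. The lists carry no p or q, and the highest peak end on chromosome 1 was 197157970, beyond the end of that chromosome in GRCm38 and within it in mm9. Each list is sorted by signal, with lowest values of 0.0849, 0.0850 and 0.0965 in C57BL/6J and 0.119, 0.107 and 0.125 in A/J on Control, HF and Reversal.

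The 2 expression tables hold RefSeq transcripts with the result columns that the authors made with DESeq2, per the file headers. The authors' deposited log2 fold change and its standard error, also on the log2 scale, compare 2 diets that the table does not name. The deposited score per transcript is the likelihood ratio statistic, and each deposited p-value equals the value of a chi-square distribution with 2 degrees of freedom at that statistic, so that the test is over all 3 diets of a strain. The authors kept transcripts with an adjusted p-value up to 0.0496 in C57BL/6J and 0.0498 in A/J. From the deposited p-value and adjusted p-value the number of transcripts tested was worked out as 19658 in C57BL/6J and 20591 in A/J. Values per library were not used here, since the tables hold none, and the planned refit of each pair of diets was not run. The design had expected fold changes per pair of diets. In its place the test over 3 diets was reported, with signs of the deposited contrast. Gene symbols were matched from a RefSeq gene table of GRCm38, used for names only: 675 of 681 C57BL/6J transcripts and 690 of 699 A/J transcripts matched. A gene with several transcripts, 120 in C57BL/6J and 126 in A/J, was represented by the one with the smallest p.

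Peaks of the 3 lists of a strain were merged where they overlapped by at least 1 bp. HF-gained regions held an HF peak and no Control peak, and HF-lost regions the reverse. For each class the share with a Reversal peak was given with a 95% Wilson interval, and the difference of both shares with a Newcombe interval in percentage points. It was repeated in bins of 20% of the peak rank within the HF or Control list. Shared regions between lists were counted in the union of all 6 lists, and shared bases with bedtools 2.31.1. Since each strain and diet had 1 list, no test was run on regions. Peaks near changed genes were not analysed here, because no gene positions in mm9 were at hand.

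The gene lists, 25 in all, were fixed before the data were examined: cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipid droplet, bile acid transport, glucose metabolism, acute phase, interferon response, xenobiotic metabolism, male-biased and female-biased genes, clock, endoplasmic reticulum stress, heat shock, NRF2, cell cycle and chromatin modifiers, and markers of macrophages, lymphocytes, stellate cells, endothelium, cholangiocytes, adipocytes, erythroid cells and exocrine pancreas. Positive against negative fold changes of a list's changed members were set against those of all other changed genes of the strain with Fisher's exact test on both sides, for lists with at least 5 changed members, and adjusted by Benjamini-Hochberg within the strain over 8 lists in C57BL/6J and 9 in A/J. The count adjusted over the list alone is a lower bound, since members outside the table have no p. Sign agreement between strains was tested with an exact binomial test on both sides. A fold change was said to leave out 0 when it exceeded 1.96 standard errors.

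Named genes followed a rule fixed before the data were examined: per strain the 6 largest positive and 6 largest negative fold changes among genes at or above the median mean level, leaving out unnamed models, up to 4 genes with the smallest adjusted p of each list, and 5 genes of each sign class shared by the strains. For regions it was the 3 with the highest signal of each class, of which some are named here, as are some of the genes. The fifth macrophage gene, Cd5l, lies outside that rule and was named after its value was seen. Alternatives fixed in advance were the 20000 and the 10000 strongest peaks of each list, lists of equal length, peaks in the stronger 50% of a list, overlap of 50% of the shorter peak, absence only where no peak lay within 1000 bp, autosomes only, an adjusted p threshold of 0.01, a log2 fold change of at least 1 in size, a minimum mean level and list members of 1 list only. The counting of regions was run on simulated lists of as many regions as each strain had, 40891 or 40209, and recovered 12 of 12 counts per strain. Simulated peaks of a region always overlapped and separate regions never did, so that this checks the counting alone. Weak peaks missed by a list were not simulated. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used.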

Results

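Liver of C57BL/6J and A/J mice, a pair of inbred strains, was profiled by FAIRE-seq, which recovers DNA that crosslinks poorly to nucleosomes and so marks open chromatin, and by RNA-seq. Mice ate control diet for 16 weeks (Control), high fat diet for 16 weeks (HF), or high fat diet for 8 weeks and then control diet for 8 weeks (Reversal). Each of the 12 combinations of strain, diet and assay held 2 libraries, 24 in all. The question posed by the series is whether open chromatin that changed on high fat diet stayed changed after the return to control diet. No group was profiled at the end of 8 weeks of high fat diet. The words kept, lost and still absent thus compare separate groups and describe no course over time. The shorter high fat diet of the Reversal group cannot be told apart from its return to control diet. Open chromatin was given as 1 peak list per strain and diet, so that differences between lists have no replicate check and no test was run on them. Expression was given as 1 table per strain of the transcripts that differed between the 3 diets. Sequencing depth per library is not given in the sources used here.

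In C57BL/6J liver the lists held 35465 peaks on Control, 33371 on HF and 32727 on Reversal, covering 20.3, 19.2 and 19.8 Mb. In A/J liver they held 36410, 33963 and 35332 peaks, covering 24.0, 21.5 and 21.8 Mb. The median peak width was 410 bp on Control, 423 bp on HF and 451 bp on Reversal in C57BL/6J, and 503, 481 and 470 bp in A/J. Serial numbers in the peak names ran to a total of 244259 for C57BL/6J Control and 116089 for A/J Reversal, so that the lists held between 14.5% and 30.4% of the peaks that had been numbered. A region without a peak is therefore one that did not reach its list, and it can still have been open.

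In C57BL/6J liver, 4229 regions were open on HF and not on Control, which is 12.9% of HF regions (95% Wilson interval 12.5 to 13.3). On Reversal 2122 of these HF-gained regions held a peak, a share of 50.2% (48.7 to 51.7). A larger set of 6300 regions was open on Control and not on HF, 18.1% of Control regions (17.7 to 18.5). Of these HF-lost regions 4736 were without a peak on Reversal, a share of 75.2% (74.1 to 76.2). Most open chromatin did not differ by this measure, since 26834 of the 40891 regions (65.6%) held a peak on all 3 diets. The share of regions with a Reversal peak was 25.4 percentage points higher among HF-gained than among HF-lost regions (23.5 to 27.2), so that the Reversal list was nearer to the HF list than to the Control list. Intervals on shares of regions cover counting error only.

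In A/J liver the order was the opposite. There, 2640 regions were gained on HF, 7.93% of HF regions (7.65 to 8.23), and 516 of them (19.5%, 18.1 to 21.1) held a peak on Reversal. HF-lost regions numbered 5441, 15.1% of Control regions (14.7 to 15.5), and 2335 of them (42.9%, 41.6 to 44.2) were without a peak on Reversal. The other 57.1% of lost regions (55.8 to 58.4) held a Reversal peak. All 3 diets shared 29389 of the 40209 regions (73.1%). The share with a Reversal peak was lower among HF-gained than among HF-lost regions, by -37.5 percentage points (-39.5 to -35.5). With 1 list per strain and diet, the difference between the strains was not tested.

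**Figure D1:**
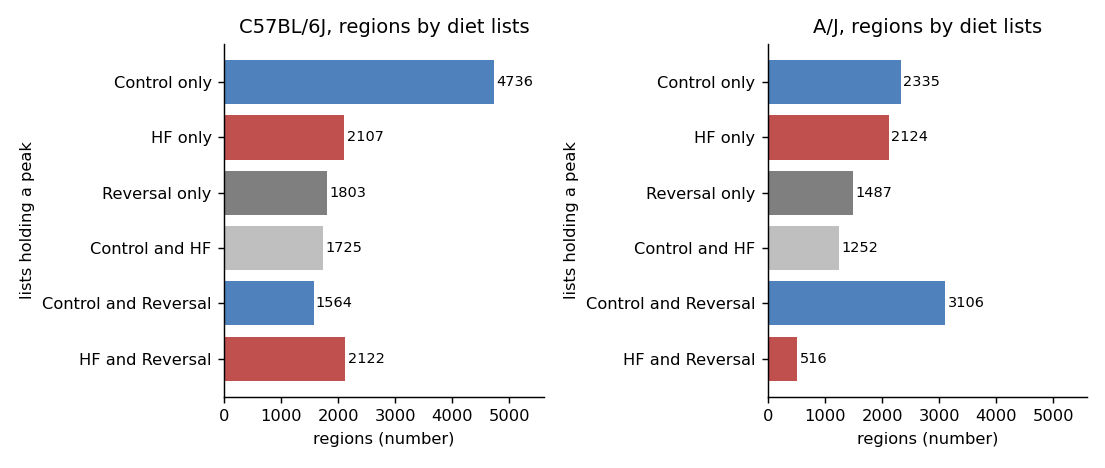
Number of regions (horizontal axis) by which diet lists held a peak (vertical axis), for C57BL/6J and A/J liver; regions open on all 3 diets are left out, red bars are HF-gained regions, blue bars HF-lost regions, light grey bars regions absent only on Reversal and dark grey bars regions found only on Reversal. In C57BL/6J the longest bar is Control only with 4736 regions, and in A/J it is Control and Reversal with 3106.

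Regions that differed between diets were weak in every list. No HF-gained or HF-lost region had its peak in the strongest 20% of its list by signal, and the median rank of such peaks lay at 85.2% of the HF list for gained and 86.0% of the Control list for lost regions in C57BL/6J, and at 88.7% and 88.0% in A/J. Among C57BL/6J regions ranked at 60 to 80%, 66.4% of 1260 gained regions held a Reversal peak (63.8 to 69.0) against 34.7% of 1915 lost regions (32.6 to 36.9). In A/J the corresponding shares were 17.5% of 593 gained regions (14.7 to 20.8) and 86.5% of 1339 lost regions (84.5 to 88.2). The direction within each strain held in the 3 rank bins from 40 to 100%, but only 61 gained and 22 lost C57BL/6J regions had a peak in the stronger 50% of a list, and among these the difference was -6.41 percentage points (-22.7 to 15.9). Among C57BL/6J regions with a peak in at least 1 A/J list, a restriction chosen after the data were seen, the difference was 5.38 percentage points.

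**Figure D2:**
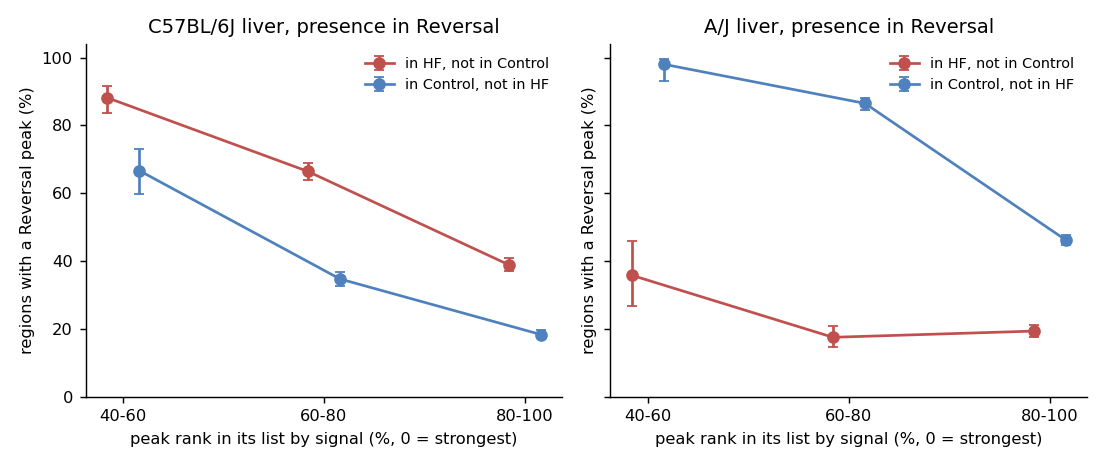
Share of regions with a Reversal peak (vertical axis, percent) by the rank of the HF or Control peak in its own list (horizontal axis, percent, strongest peaks at 0), for HF-gained (red) and HF-lost (blue) regions, with 95% Wilson intervals as bars. In C57BL/6J the gained regions lie above the lost regions in each bin, by 21.5, 31.7 and 20.6 percentage points, and in A/J they lie below, by -62.2, -68.9 and -26.8.

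Positions are given in mm9, 1-based, and genes at them are not named, because the gene annotation at hand is of another assembly. The strongest C57BL/6J region gained on HF and kept lay on chromosome 4 from 140836962 to 140838040, with a signal of 0.241 on HF and 0.175 on Reversal, and it held a peak in all 3 A/J lists. The next in this class lay on chromosome 2 from 26455532 to 26455898 and from 27480304 to 27480858. The strongest region gained and not kept lay on chromosome 6 from 49186386 to 49186680 with a signal of 0.299 and had no peak in any A/J list. Among HF-lost regions the strongest was on chromosome 16 from 19713902 to 19714196, at 0.210 on Control, and it held a Reversal peak at 0.117. In A/J the strongest gained and kept region was on chromosome 18 from 26748562 to 26748883, at 0.309 on HF and 0.170 on Reversal. The strongest A/J region gained and not kept, on chromosome 1 from 111744254 to 111744578, had a signal of 0.262 and held a peak in all 3 C57BL/6J lists. The A/J region with the strongest lost peak lay on chromosome 6 from 121121051 to 121121577, at 0.453 on Control and 0.352 on Reversal. Signals are the values in the deposited lists, on a scale that is not given, and serve to rank peaks within a list only.

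Lists overlapped less between strains than between diets, which describes the lists and was not tested. The processing notes name no assembly other than mm9, and whether reads of both strains map to it alike was not examined. A strain difference in open chromatin cannot be told apart from a difference in mapping here. At the same diet, C57BL/6J and A/J shared 49.1% of regions on Control (48.6 to 49.5), 64.6% on HF (64.2 to 65.1) and 58.4% on Reversal (57.9 to 58.9), each as a share of the regions open in either strain. These values do not follow the diet. A/J HF shared 56.0% with C57BL/6J Control and 66.1% with C57BL/6J Reversal, in each case more than the A/J list of the same diet. C57BL/6J Control had the lowest share with each A/J list, and A/J HF the highest with each C57BL/6J list. Within C57BL/6J, Control and HF shared 73.2% of regions (72.8 to 73.7), Control and Reversal 73.3% (72.8 to 73.7), and HF and Reversal 80.4% (80.0 to 80.8). Within A/J, Control and HF shared 79.2% (78.8 to 79.6), Control and Reversal 85.4% (85.0 to 85.7), and HF and Reversal 79.0% (78.6 to 79.5). By covered bases the corresponding values were 72.5%, 76.3% and 78.5% in C57BL/6J and 78.7%, 82.0% and 78.6% in A/J. Of the 51034 regions open in any of the 6 lists, 20799 were open in all of them.

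Liver transcripts that differed between the 3 diets numbered 681 in C57BL/6J, from 461 genes, and 699 in A/J, from 491 genes, at the adjusted p threshold of 0.05 in the authors' deposited tables. These were 3.46% and 3.39% of the transcripts tested, whose number follows from the adjusted p-values. The log2 fold change in the authors' deposited tables compares 2 of the 3 diets that the tables do not name, so that the comparisons of HF with Control, of Reversal with Control and of HF with Reversal cannot be given apart. Signs below are those of that contrast and are read neither as up nor as down on high fat diet. The 95% interval of the fold change left out 0 in 287 C57BL/6J genes (171 positive, 116 negative) and 263 A/J genes (135 positive, 128 negative). In 95 and 113 genes the fold change was under 1 standard error, and there the difference between diets lies with the diet that is not in the contrast.

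In C57BL/6J liver, 12 of the 24 listed genes of cholesterol synthesis and uptake differed between diets, 11 with a negative fold change against 1 with a positive one. The interval left out 0 in 6 of the 11. Of the 12, 3 were under 1 standard error, near the share among the other changed genes (92 of 449, 20.5%). For Msmo1 and Idi1 much of the difference lies with the diet outside the contrast: for Msmo1 64.3 of a statistic of 73.6 is left after the squared ratio of fold change to standard error is taken off, and for Idi1 29.3 of 39.4, from the authors' deposited table. Msmo1, a sterol demethylation enzyme, had a log2 fold change of -0.48 ± 0.16 (SE) and Idi1, an enzyme of isoprenoid synthesis, -0.68 ± 0.22 in the authors' deposited table, while Mvd and Fdft1 had -0.28 ± 0.19 and -0.33 ± 0.16. Genes higher in male than in female liver leaned the same way, with 8 of 9 negative, 5 of them with an interval that left out 0, and 3 of the 9 under 1 standard error: C8a and C6, which encode complement proteins, had -0.74 ± 0.10 and -0.92 ± 0.15, the organic anion transporter gene Slco1a1 -0.75 ± 0.13 and the urinary protein gene Mup20 -0.86 ± 0.18 in the authors' deposited table. Each sign split was set against that of the other changed genes with Fisher's exact test, and both passed adjustment over the 8 lists tested (adjusted p 0.00353 and 0.0199). The male list no longer passed with members of more than 1 list left out (adjusted p 0.0622). Adjusted over the list alone, at least 12 cholesterol genes and at least 9 genes higher in male liver passed 0.05. All changed members of every list did so, and this adds no support.

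Other C57BL/6J lists did not pass that test. Of the endoplasmic reticulum stress and amino acid response list 7 of 15 genes differed, 6 of them negative (adjusted p 0.0622), with Asns, the asparagine synthetase gene, at -2.04 ± 0.47, Creld2 at -0.64 ± 0.25 and Herpud1 at -0.29 ± 0.14, against Chac1, a glutathione-degrading enzyme gene, at 1.16 ± 0.43 in the authors' deposited table. All 5 changed interferon response genes were positive (adjusted p 0.139), among them Gbp7 at 0.60 ± 0.20 and Psmb9 at 0.53 ± 0.16 in the authors' deposited table. The sterol exporter genes Abcg5 and Abcg8 had 0.71 ± 0.11 and 0.65 ± 0.12 in the authors' deposited table, within a bile acid and sterol transport list of which 4 of 18 genes differed, too few to test. Acute phase genes split 4 to 3 (adjusted p 1): Saa1 and Saa2 had -0.18 ± 0.21 and -0.18 ± 0.23 with statistics of 32.6 and 29.7, so that the unnamed diet outside the contrast stood apart, and Il1b had 1.52 ± 0.41 in the authors' deposited table. Glucose metabolism genes split 4 to 1 (adjusted p 0.540), xenobiotic metabolism genes 6 to 2 (adjusted p 0.546) and clock genes 1 to 5 (adjusted p 0.139).

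The largest fold changes among well expressed C57BL/6J genes were those of Errfi1, an inhibitor of the EGF receptor, at 1.73 ± 0.19 (adjusted p 4.25e-16), Plk3 at 1.59 ± 0.43, Slc25a25 at 1.35 ± 0.21, the nuclear long noncoding RNA Neat1 at 1.31 ± 0.18, the serine dehydratase gene Sds at 1.24 ± 0.38 and Gpcpd1 at 1.20 ± 0.15, from DESeq2 in the authors' deposited table. On the negative side stood Csad, which acts in taurine synthesis, at -1.50 ± 0.39, Arrdc3 at -1.14 ± 0.22, Tsku at -1.10 ± 0.18 (adjusted p 4.74e-25), C6, Mup20 and Osgin1, the last at -0.83 ± 0.21, in the authors' deposited table. At lower mean levels, the hepatokine gene Fgf21 had -2.97 ± 0.32 and the female-biased cytochrome gene Cyp2b9 had 5.12 ± 0.85 in the authors' deposited table.

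In A/J liver, genes of fatty acid oxidation and targets of the fatty acid receptor PPAR alpha differed between diets in 15 of 26 cases, all 15 with a positive fold change, 12 with an interval that left out 0 (Fisher's exact test against the other changed genes, adjusted p 0.000475 over 9 lists). The fatty acid hydroxylase genes Cyp4a10 and Cyp4a14 had 1.63 ± 0.11 and 3.79 ± 0.59, Vnn1 2.51 ± 0.27, the lipase inhibitor gene Angptl4 1.13 ± 0.15 and the thioesterase gene Acot2 0.93 ± 0.18 in the authors' deposited table. Lipid droplet and fatty acid uptake genes went the same way, 8 of 8 positive (adjusted p 0.0169), including Plin2, which coats lipid droplets, at 0.47 ± 0.12, Apoa4 at 0.65 ± 0.12, G0s2 at 0.67 ± 0.25 and Plin5 at 0.27 ± 0.13 in the authors' deposited table. In these named genes most of the difference lies with the diet outside the contrast. With the squared ratio of fold change to standard error taken off, 94.7 of a statistic of 109 is left for Plin2. For Apoa4 it is 103 of 130, for G0s2 29.4 of 36.3 and for Plin5 34.3 of 38.7, from the authors' deposited table. At an adjusted p threshold of 0.01 for genes the lipid droplet call was lost (adjusted p 0.122). Adjusted over the list alone, at least 15 and at least 8 genes of these lists passed 0.05, which adds no support, since all changed members of every list did.

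Genes with a known sex bias also split by sign in A/J. All 12 changed genes higher in male liver had a negative fold change (adjusted p 0.000689) and all 9 changed genes higher in female liver a positive one (adjusted p 0.0112), by the same exact test. The male list held Mup1 at -1.36 ± 0.18, Mup2 at -1.12 ± 0.18 and Nudt7 at -0.31 ± 0.12, and the female list held the cytochrome genes Cyp3a44 at 1.11 ± 0.12, Cyp3a41b at 1.07 ± 0.20 and Cyp3a41a at 1.05 ± 0.21 in the authors' deposited table. In all, 15 Mup genes differed and all were negative, from -1.46 to -0.49, with Mup18, Mup17, Mup11, Mup12 and Mup19 between -1.46 and -1.24 in the authors' deposited table. Mup copies are nearly identical and share reads, as do the Cyp3a41 copies, so that values of single copies are uncertain. The female list no longer passed at an adjusted p threshold of 0.01 for genes (adjusted p 0.0801), and with members of more than 1 list left out it had 4 changed genes of 13, all positive, too few to test. Adjusted over the list alone, at least 12 and at least 9 genes passed 0.05, which again adds no support.

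**Figure D3:**
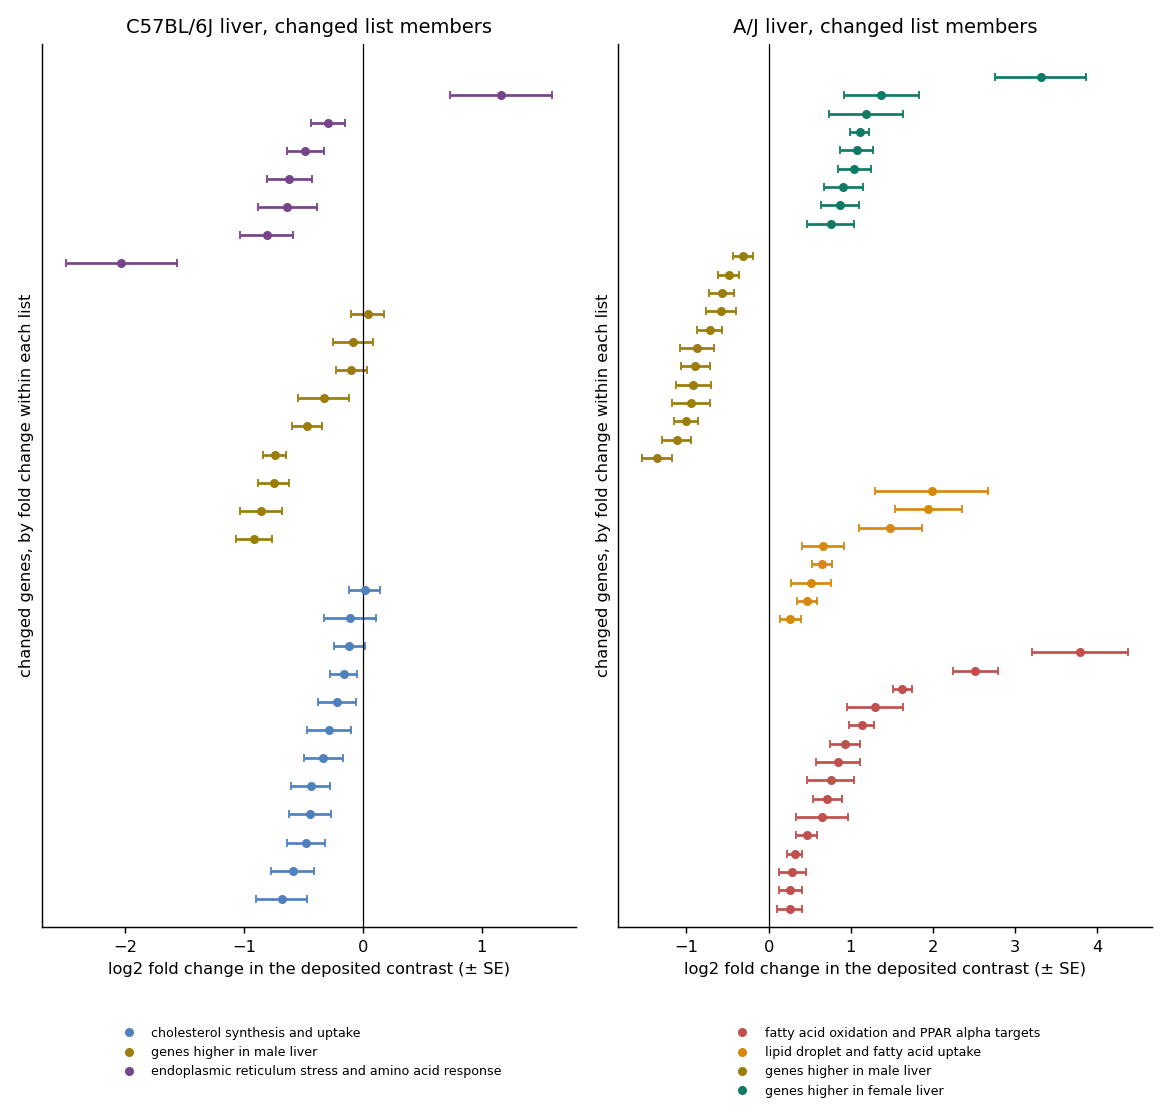
Log2 fold change in the deposited contrast (horizontal axis, bars ± 1 SE) of each changed gene (vertical axis, ordered by fold change within a list) of 3 lists in C57BL/6J liver and 4 lists in A/J liver, coloured by list. In C57BL/6J 11 of 12 cholesterol genes and 8 of 9 male-biased genes lie below 0, and in A/J the 15 fatty acid oxidation genes lie above 0 and the 12 male-biased genes below.

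Clock genes differed between A/J diets with little change in the deposited contrast. Of the 20 listed genes of the circadian clock and its output 11 differed, 7 positive and 4 negative (adjusted p 0.819), and 8 of the 11 had a fold change under 1 standard error. Per3, a repressor of the clock, had 0.09 ± 0.15 with a likelihood ratio statistic of 202, and the transcription factor genes Tef and Dbp had -0.02 ± 0.11 and 0.00 ± 0.14 with statistics of 148 and 134 in the authors' deposited table. Usp2 had 0.68 ± 0.30 with a statistic of 143, and outside this list G6pc, the gene of the last step of glucose output, had 0.03 ± 0.15 with a statistic of 129 in the authors' deposited table. In C57BL/6J 6 clock genes differed, 3 of them under 1 standard error, with statistics of 33.5 for Nfil3 and 25.2 for Hlf in the authors' deposited table.

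**Figure D4:**
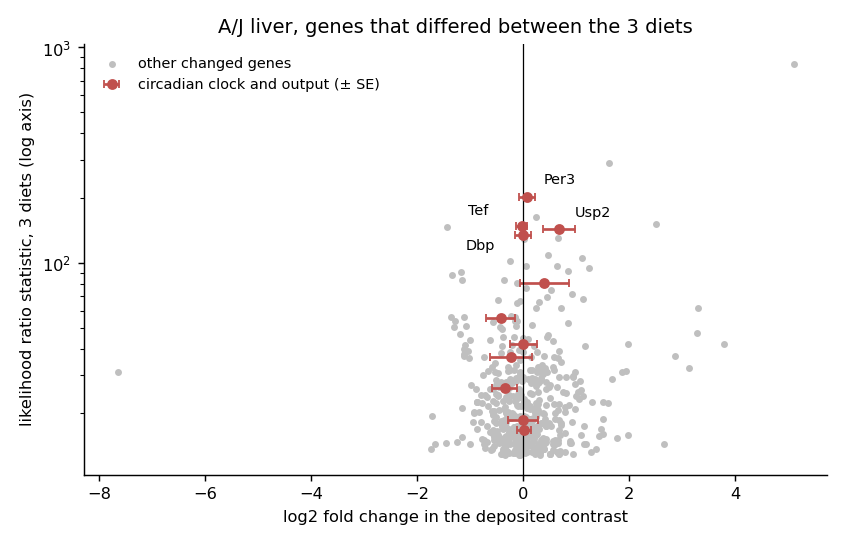
Likelihood ratio statistic over the 3 diets (vertical axis, log scale) against the log2 fold change in the deposited contrast (horizontal axis) for the 491 genes that differed in A/J liver, where red points are clock genes with bars of ± 1 SE and grey points are the other genes. Per3, with a statistic of 202, Tef and Dbp lie near a fold change of 0.

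Macrophage markers differed in A/J with 5 of 5 genes positive, which did not pass (adjusted p 0.111). They were the antigen presentation genes H2-Aa at 0.98 ± 0.25, H2-Ab1 at 0.98 ± 0.26 and H2-Eb1 at 1.15 ± 0.45, the scavenger receptor gene Marco at 1.09 ± 0.41 and Cd5l in the authors' deposited table. In C57BL/6J the only changed member of this list was Mmp12, a macrophage elastase gene, at -2.38 ± 0.70 in the authors' deposited table. No gene of the lymphocyte, stellate cell, endothelial or cholangiocyte lists differed in either strain. Among the other markers, Cfd of the adipocyte list had 0.56 ± 0.41 in C57BL/6J, and Car3 of that list -0.21 ± 0.11, the erythroid gene Alas2 -0.59 ± 0.13 and the pancreatic gene Cela1 -0.67 ± 0.19 in A/J in the authors' deposited table.

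The remaining fixed lists gave few changed genes or no lean in sign. In C57BL/6J liver 4 of 19 fatty acid synthesis genes differed (3 positive, 1 negative), with Me1 at 0.00 ± 0.15, and 3 of 26 fatty acid oxidation genes (2 positive, 1 negative), 2 of 18 lipid droplet genes (1 of each sign), 2 of 20 genes higher in female liver (both positive), 3 of 9 heat shock genes (all negative), 1 of 11 NRF2 genes (negative) and 2 of 17 cell cycle genes (both positive) in the authors' deposited table. In A/J liver fatty acid synthesis genes split 4 to 2 (adjusted p 0.882), with Fads1 at 0.37 ± 0.10 and Fads2 at 0.51 ± 0.13, glucose metabolism genes 3 to 2 (adjusted p 1) and xenobiotic metabolism genes 8 to 9 (adjusted p 0.908) in the authors' deposited table. All 4 changed interferon response genes were positive, among them Gbp3 at 1.13 ± 0.25 and Usp18 at 1.05 ± 0.22, and 2 of 3 bile acid transport genes were, with Cyp7b1 at -0.91 ± 0.21 and Nr0b2 at 0.70 ± 0.23 in the authors' deposited table. Single A/J genes differed in the cholesterol (negative), acute phase (Mt1, positive), endoplasmic reticulum stress (Herpud1, positive), cell cycle (Cdkn1a, positive) and chromatin modifier (Dnmt3b, negative) lists, and 2 in the heat shock (both negative) and NRF2 (both positive) lists. No chromatin modifier gene differed in C57BL/6J. In every list the changed genes, which passed adjustment over all transcripts, also passed 0.05 adjusted over the list alone, so that each count is a lower bound there.

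The strains had 75 changed genes in common, which is 16.3% of the C57BL/6J and 15.3% of the A/J genes. At the level of transcripts 107 were shared, against 24.2 if the lists of both strains had been drawn independently. The value of 24.2 takes every tested transcript as equally likely to pass, whatever its level, and transcripts of the same gene as separate. The excess over it is therefore not read as a shared response to diet. Of the 75 genes 40 had the same sign in both strains (53.3%, exact binomial p = 0.644 across genes, which are not independent replicates), and of the 24 whose intervals left out 0 in both strains 10 did (exact binomial p = 0.541). This comparison takes the contrast to be the same in both tables, which neither table states. The pseudogene transcript Cyp4b1-ps2 had the highest statistic in each strain, 435 in C57BL/6J and 842 in A/J, but a fold change of 0.15 ± 0.29 in the former and 5.11 ± 0.23 in the latter in the authors' deposited tables. Ppp1r3c, a glycogen targeting subunit gene, had -0.65 ± 0.18 and -0.74 ± 0.21, and the glutathione transferase gene Gstp1 -0.69 ± 0.17 and -0.80 ± 0.17 in C57BL/6J and A/J in the authors' deposited tables. Fgf21 had -2.97 ± 0.32 in C57BL/6J and 0.65 ± 0.32 in A/J, and the urea cycle gene Cps1 0.30 ± 0.11 and -0.23 ± 0.10 in the authors' deposited tables. Most of the Cps1 difference lies with the diet outside the contrast. With the squared ratio of fold change to standard error taken off, 31.2 of a statistic of 38.4 is left in C57BL/6J and 51.9 of 56.9 in A/J. For Fgf21 in A/J it is 22.3 of 26.5, while in C57BL/6J its difference lies within the contrast. For Ppp1r3c it is 15.1 of 28.6 and 23.7 of 36.6, and for Gstp1 12.1 of 28.1 and 2.16 of 24.4.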

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

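The tests on Control peaks of the other strain and on weak peaks were chosen after the result was seen, while lists of 20000 peaks and peaks in the stronger 50% of a list were settings fixed in advance. The strains moved in opposite directions: the share of regions with a Reversal peak was 25.4 percentage points higher among HF-gained than among HF-lost regions in C57BL/6J, and the corresponding value in A/J was -37.5. This difference between the strains was not tested, since each strain and diet had 1 list.

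Unequal list lengths do not account for either direction, since lists of 20000 peaks each gave 42.3 percentage points in C57BL/6J (39.6 to 44.9) and -47.7 in A/J (-50.5 to -44.7). In A/J the difference was -62.2 (-71.2 to -51.0) among peaks ranked at 40 to 60% of their list. For these ranks it argues against peaks near the limit of the list that held them as the source of the A/J direction. How near the limit such a region lay in a list without its peak is not known, so that weak peaks are not excluded. The stronger 50% gave -20.0 in A/J (-62.4 to 14.1). That interval holds both signs and rests on 5 gained and 9 lost regions, too few to decide. Weak peaks stay open in C57BL/6J, where ranks of 40 to 60% gave 21.5 (13.8 to 29.2). There the stronger 50% gave -6.41 (-22.7 to 15.9), from 61 gained and 22 lost regions. A candidate explanation is that the C57BL/6J Control list and the A/J HF list each stood apart as a whole. Regions found on HF only held a Control peak of the other strain more often than regions found on Control only. The gap was 41.6 percentage points in C57BL/6J (39.2 to 43.9) and 59.8 in A/J (57.4 to 62.1). Its sign was the same in both strains, so it cannot tell which list stood apart. Within A/J, HF shared fewer regions with the other lists (79.2% and 79.0%) than those shared with each other (85.4%). Yet A/J HF shared more with each C57BL/6J list (56.0%, 64.6% and 66.1%) than A/J Control did (49.1%, 56.9% and 58.8%). The lists also differed in median signal, at 0.167, 0.177 and 0.216 in C57BL/6J on Control, HF and Reversal. In A/J these medians were 0.321, 0.257 and 0.331. By this value Reversal lay nearest to HF in C57BL/6J and nearest to Control in A/J, as in the shared regions. Whether such a difference between lists gave either direction was not tested, and the scale of the signal is not given. Persistence of a change made by the high fat diet in C57BL/6J cannot be told apart from weak peaks or from a list that stood apart, with 1 list per strain and diet.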

How the results depend on the processing

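The alternatives below were fixed before the data were examined, except 4 chosen after the results were seen: 1 count per gene, only fold changes whose interval leaves out 0, Mup genes left out, and only regions with a peak in the other strain. Of 179 values under an alternative, for 38 results, 75 moved (a share or difference out of its 95% interval, a count by more than 1.5 times), 3 changed direction, 3 gene list calls were lost, 1 was gained and 97 held, not counting lists left with too few genes to test.

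In C57BL/6J, the 20000 strongest peaks of each list gave 2196 HF-gained and 2166 HF-lost regions, 67.1% of gained regions kept and a difference of 42.3 percentage points. The 10000 strongest gave 808 and 795 regions, 73.8% kept, 84.5% of lost regions still absent and 58.3 points. Lists of equal length gave 55.6% kept and 69.5% still absent. Peaks in the stronger 50% of a list gave 61 and 22 regions, 75.4% kept, 18.2% still absent and -6.41 points, the opposite sign. Absence only where no peak lay within 1000 bp gave 52.9%, 76.6% and 29.4 points. Regions with a peak in A/J gave 5.38 points.

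In A/J, the 20000 strongest peaks gave 1615 and 1790 regions, 33.4% of lost regions still absent and -47.7 points, and the 10000 strongest 878 and 903 regions, 25.6% kept, 30.5% still absent and -43.9 points. Lists of equal length gave 22.5% kept and 39.6% still absent. Peaks in the stronger 50% of a list gave 5 and 9 regions, 80.0% kept, 0% still absent and -20.0 points. Absence within 1000 bp gave 39.0% still absent and -42.0 points, and regions with a peak in C57BL/6J -45.2 points.

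Shared regions, in the order Control and HF within C57BL/6J, Control and HF within A/J, and between strains on Control, HF and Reversal, came to 80.3%, 84.3%, 57.8%, 72.8% and 68.0% with 20000 peaks. They came to 85.2%, 83.6%, 63.7%, 80.5% and 74.6% with 10000 peaks, 74.6%, 80.8%, 50.7%, 65.2% and 59.3% with equal lengths, and 76.7%, 83.1%, 54.9%, 69.5% and 64.3% with the 1000 bp margin. Overlap of 50% of the shorter peak moved the last 4 to 78.4%, 50.8%, 65.8% and 58.9%, and autosomes alone moved the strain overlap to 49.8% on Control and 65.3% on HF.

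At an adjusted p threshold of 0.01, 372 C57BL/6J and 447 A/J transcripts remained in the authors' deposited tables, 29 genes were changed in both strains with the same sign in 44.8%, below 50%, and 2 A/J lists passed. A log2 fold change of at least 1 in size left 85 and 80 transcripts and 0 shared genes, so that no share with the same sign exists there. A mean level at or above the median of the table left 341 and 350 transcripts and 43 shared genes. With members of more than 1 list left out, 1 C57BL/6J list passed, and 3 A/J lists in place of 4, since the female list had 4 changed genes left, too few to test. With only fold changes whose interval leaves out 0, the A/J xenobiotic list leaned the other way (adjusted p 1) and the C57BL/6J endoplasmic reticulum stress list passed (adjusted p 0.0250).

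Not run were the alternatives that need values per library (another test, filters on low counts, leaving out a replicate, a replicate block, a pseudocount), those of each pair of diets, and distances of peaks to genes. No paired analysis was possible because the tables hold no values per library and the labels pair no libraries across diets.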

Other observations

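All tests in this part were chosen after the results were seen. The sex chromosomes took unlike shares of the lists: chromosome X held 3.85%, 3.40% and 2.92% of C57BL/6J peaks on Control, HF and Reversal and 1.51%, 1.98% and 1.51% of A/J peaks, and chromosome Y held 152, 120 and 103 C57BL/6J peaks and 50, 76 and 57 A/J peaks. Among C57BL/6J regions chromosome X held 10.8% of those open on Control and HF only and 0.754% of those open on HF and Reversal only, and among A/J regions 7.02% of those open on HF only.

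In C57BL/6J 4 of the 7 changed acute phase genes had a fold change under 1 standard error, against 91 of 454 other changed genes (Fisher's exact p 0.0358, adjusted p 0.286 over 8 lists), which did not pass. None of the 15 changed A/J genes of fatty acid oxidation did (adjusted p 0.125 over 9 lists).

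Clock genes differed between A/J diets outside the deposited contrast: 8 of 11 changed clock genes had a fold change under 1 standard error, against 105 of 480 other changed genes (21.9%, Fisher's exact p 0.000561, adjusted p 0.00505 over 9 lists). A candidate explanation is that the libraries of 1 diet came from another time of day, and another that a diet acts on the clock. These cannot be told apart, because harvest times are not given in the sources used here and both predict the same values. Harvest times per animal, or both diets sampled around the day, would separate them.

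Genes higher in male liver had negative and genes higher in female liver positive fold changes in the deposited A/J contrast. Reads shared between Mup copies do not account for it, since without Mup genes all 7 changed male-biased genes were negative (Fisher's exact p 0.00486, adjusted p 0.0146). Animals of the other sex in 1 diet group would place Xist and Y-linked transcripts among those that differed, and 0 of 5 such transcripts are in the deposited A/J table. Their absence cannot decide this, since the table gives no values for these transcripts and does not show that they were tested. The chromosome Y peaks come from other libraries. A diet effect on growth hormone signalling, which sets the sex bias of liver genes, may also account for it and was not tested, and sex records and hormone profiles of the same mice would test both.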
